A study of Homo sapiens with 48 samples.

How the data were processed

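Total RNA of 8 bladder cancer cell lines was extracted with Trizol, per the labels' protocols, and libraries were sequenced as paired-end reads. The labels name a TruSeq kit and also a strand-specific protocol, and whether the counting used strand is not given in the sources used here, so genes with antisense or overlapping partners are uncertain. The growth label spells VMCUB as VMCUB1. The deposited table holds whole-number counts per Ensembl gene for 48 libraries. Per the submitters' processing notes, the authors used STAR 2.7.3a and RSEM 1.3.1 with the hg38 build. RSEM gives estimated counts that need not be whole, and how these became the deposited whole-number counts, and with which annotation, is not given in the sources used here. Intervals on counts cover counting error only, since reads carried no molecular identifiers.

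The table had 35535 genes, 3756 of them at 0 in all libraries, and 0 entries that name no gene. Symbols came from a gene name table for 35414 genes, otherwise from GENCODE 29, which matched 35497 and gave coordinates on GRCh38, the same assembly as hg38. Library totals ranged from 26481418 to 50916911 counts, and mitochondrial genes held 1.75% to 6.18% of them. Libraries were grouped by cell line and treatment from their labels, 3 per group.

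Everything below was computed from the counts with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and with Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9. In each line, CPI-0209 was compared with DMSO on its 6 libraries, with TMM scaling, filterByExpr, edgeR's robust quasi-likelihood test with 4 residual degrees of freedom, and Benjamini-Hochberg adjustment to a threshold of 0.05. The shared response was tested on counts summed over replicates, 16 sums, with cell line and treatment as terms. Differences between lines were tested with an F test of the 7 interaction terms on all 48 libraries. SE is the absolute log2 fold change divided by the square root of the F statistic. CPM used TMM-scaled library sizes. Where the lower group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% counting interval. No count of other series entered.

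The 24 gene lists, the tests and the naming rule were fixed before the data were examined. The lists were PRC2, PRC1 and SWI/SNF subunits, genes reported in the literature as repressed by EZH2, HOX genes, developmental transcription factors outside the HOX clusters, luminal and basal urothelial genes, epithelial to mesenchymal transition genes, type I interferon-stimulated genes, MHC class I and class II genes, cytokines and chemokines, proliferation genes, p53 targets, cyclin-dependent kinase inhibitors, cholesterol synthesis genes, unfolded protein and integrated stress response genes, cancer/testis antigens, neuronal and housekeeping genes, and markers of fibroblasts, leukocytes and endothelium. Of their entries, 611 matched a gene and 2 did not, and CDKN1A, CDKN1C, CDKN2A, CDH1, FOXC1, HOXA9, B2M and SESN2 stand in more than 1 list. Lists with at least 5 tested members were tested against other genes with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, adjusted over the lists of a comparison. Setting genes with 0 counts to their bound left each list's median as fitted.

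The naming rule took EZH2, EZH1, EED and SUZ12 always. For the shared response it took the 15 higher and 10 lower genes with the largest change among those past the threshold, with the same direction in all 8 lines, computed from the CPM of the sums, and at least 1 CPM in the higher treatment. For each line it took the 6 higher and 4 lower such genes whose 3 CPI-0209 libraries all lay on the same side of the 3 DMSO libraries. For differences between lines it took the 10 genes with the smallest p among those called 2-fold higher in one line and 2-fold lower in another, and for lists up to 4 members with the smallest p. Loci without an established symbol were passed over. A few results that the rule took are not reported here.

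Each fit was tested on simulated counts with 200 changed genes drawn with the real means and spreads. So few cannot test scaling under the far wider real responses. By line, recovery of 2-fold changes was 60% in T24, 74% in VMCUB, 78% in KU1919 and 79% in HT1376. It was 83% in HT1197, 84% in 639V, 86% in TCCSUP and 90% in SW780. For 1.5-fold changes recovery was 7% in T24, 27% in KU1919, 39% in VMCUB and 70% to 75% in the other lines. The shared fit recovered 74% and 45%, and the interaction test 58% and 37% of changes simulated in HT1197. False calls were 5 of 124 in the shared fit and 2 of 97 in the interaction test.

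Alternatives were RLE size factors, DESeq2, no filter on low counts, thinning to the smallest library, leaving out each library or line, a replicate block, and fits of all 48 libraries. Library totals alone, removal of a transcript length trend and leaving out libraries far from their groups were added after the data were seen. Comparisons of DMSO between lines were left out, except for the level of EZH2.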

Results

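RNA sequencing measured gene expression in 8 human bladder cancer cell lines, HT1197, HT1376, KU1919, SW780, T24, 639V, TCCSUP and VMCUB. Each line was treated for 4 days with 250 nM CPI-0209, an inhibitor of EZH2, or with the vehicle DMSO. EZH2 is the catalytic subunit of Polycomb repressive complex PRC2, which methylates histone H3 at repressed genes. Every line had 3 DMSO and 3 CPI-0209 libraries, 48 libraries in 16 groups. Library totals ranged from 26481418 counts in TCCSUP CPI-0209 replicate 2 to 50916911 in HT1197 CPI-0209 replicate 1, with a median of 41665645. Cell line accounted for 88.8% of the sum of squares of log2 CPM, treatment for 3.21%, the line by treatment term for 3.69% and the spread within groups for 4.35%. All replicate pairs differed by more than sampling noise, with chi-square over degrees of freedom between 2.2 and 137.9. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Values below are log2 fold changes of CPI-0209 over DMSO ± SE, or mean CPM ± SD with n = 3 libraries per group, and adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

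EZH2 (ENSG00000106462, chromosome 7, 148807383 to 148884321, GRCh38) had a shared log2 fold change over the 8 lines of 0.03 ± 0.03 (edgeR adjusted p = 0.513), going from 74.0 ± 20.7 to 76.1 ± 22.6 CPM (SD, n = 8 lines). EZH1, the related methyltransferase (ENSG00000108799, chromosome 17, 42700275 to 42745049), stood at 0.05 ± 0.06 (adjusted p = 0.59), and EED, a core subunit (ENSG00000074266, chromosome 11, 86244544 to 86278813), at -0.11 ± 0.04 (adjusted p = 0.116). SUZ12, another core subunit (ENSG00000178691, chromosome 17, 31937018 to 32001045), fell by 0.21 ± 0.04 (adjusted p = 0.0249) and was called lower in 5 of 8 lines. In single lines EZH2 rose in HT1376 by 0.15 ± 0.05 (adjusted p = 0.0377) and in TCCSUP by 0.16 ± 0.05 (adjusted p = 0.0173). EZH1 rose in HT1197 by 0.17 ± 0.06 (adjusted p = 0.0375) and in VMCUB by 0.40 ± 0.12 (adjusted p = 0.0447), and EED fell in 639V by 0.16 ± 0.05 (adjusted p = 0.014). SUZ12 fell by 0.33 ± 0.06 in TCCSUP (adjusted p = 0.000669), 0.31 ± 0.07 in HT1376 (adjusted p = 0.00825) and 0.30 ± 0.05 in 639V (adjusted p = 0.000171). It also fell by 0.15 ± 0.05 in SW780 (adjusted p = 0.009) and by 0.12 ± 0.04 in HT1197 (adjusted p = 0.0478). Scaling by library totals turned SUZ12 in SW780 to 0.05 (adjusted p = 0.324, with a range of 0.00147 to 0.324 over all alternatives) and ended its shared fall (adjusted p = 0.159) and its call in HT1197 (adjusted p = 0.144). The shared fall also ended without HT1376, T24, 639V or TCCSUP, with adjusted p of 0.0551 to 0.0706. Leaving out 1 library at a time took adjusted p to as much as 0.233 for EZH2 in HT1376, 0.0806 for EZH2 in TCCSUP, 0.14 for EZH1 in HT1197, 0.141 for EZH1 in VMCUB, 0.177 for SUZ12 in HT1197 and 0.0506 for SUZ12 in SW780. Library totals took EED in 639V to an adjusted p of 0.0792.

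**Figure D1:**
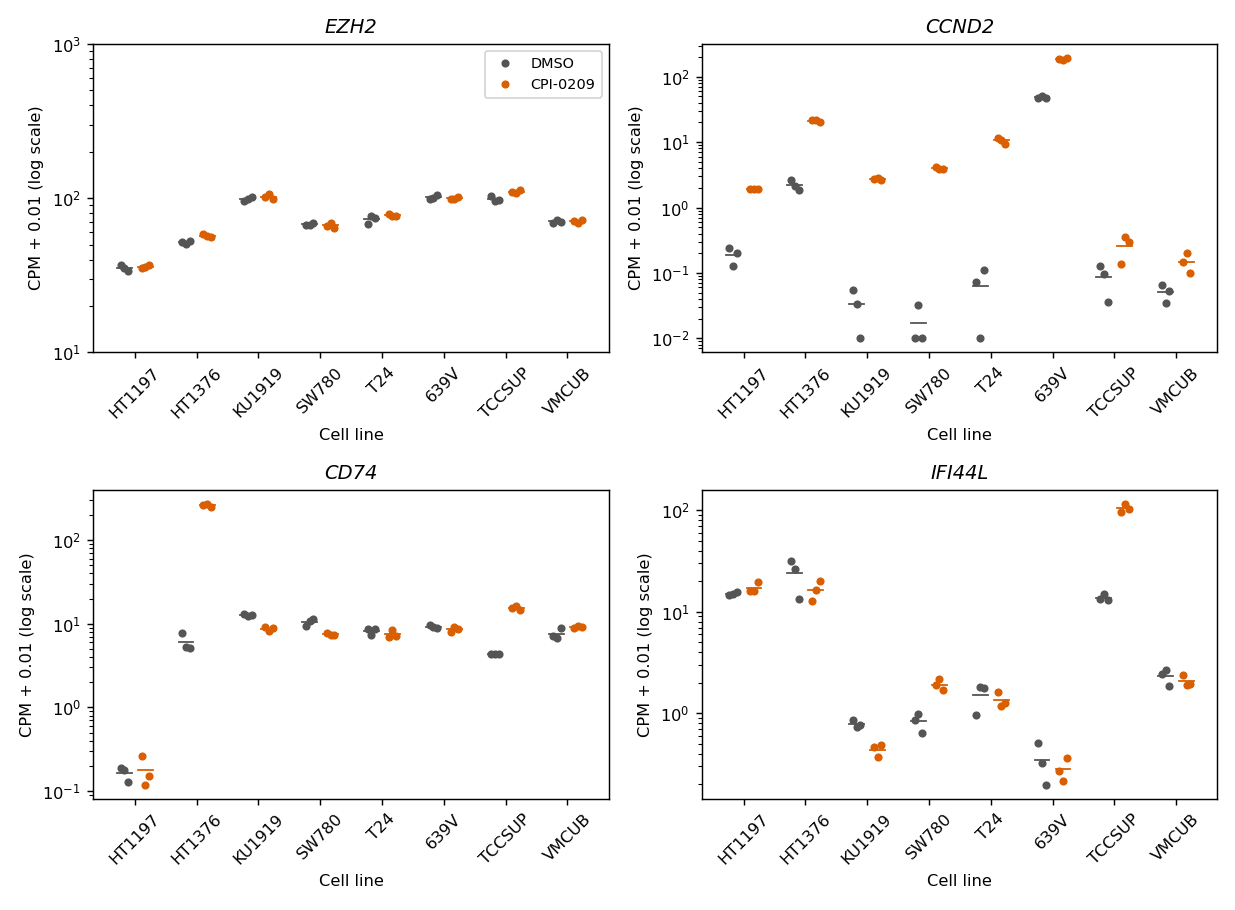
CPM plus 0.01 (log scale, y axis) of EZH2, CCND2, CD74 and IFI44L in each library of the 8 cell lines (x axis); points are single libraries, grey DMSO and orange CPI-0209, and short lines are means of 3. EZH2 stayed near its DMSO level, whereas CD74 in HT1376 went from 6.02 to 261 CPM.

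The response shared by the 8 lines was tested on the 16 sums of counts, with the line as the unit of replication. LGR5, a receptor for R-spondins and a marker of intestinal stem cells, rose by 4.49 ± 0.65 (edgeR adjusted p = 0.014) and was called higher in each of the 7 lines where it was tested. CCND2, which encodes cyclin D2 (ENSG00000118971, chromosome 12, 4273772 to 4305350), rose by 3.99 ± 0.76 (adjusted p = 0.0191). SHH, the secreted morphogen sonic hedgehog (ENSG00000164690, chromosome 7, 155799986 to 155812273), rose by 3.72 ± 0.35 (adjusted p = 0.00689), from 0.180 ± 0.266 to 2.24 ± 2.71 CPM (SD, n = 8 lines). LINGO1, a neuronal membrane protein, rose by 3.83 ± 0.64 (adjusted p = 0.0156) and was called higher in all 8 lines. MXD1, a MAX partner that opposes MYC, fell by 0.58 ± 0.10 (adjusted p = 0.0151) and was called lower in 7 of 8 lines.

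FXYD6 also rose in the shared fit by 4.64 ± 0.84 and the sulfotransferase CHST1 by 4.22 ± 0.54. The kidney transcription factor PAX2 rose by 4.17 ± 0.84 and PRIMA1 by 3.82 ± 0.71. GATA4 rose by 3.63 ± 0.93, RAI2 by 3.62 ± 0.47 and HCN4 by 3.58 ± 0.55. The germ cell gene TEX15 rose by 3.38 ± 0.43, the axonal motor KIF1A by 3.31 ± 0.72 and DMBT1 by 3.19 ± 0.61. RFPL4A, whose reads could belong to the near-identical copy RFPL4AL1, rose by 4.86 ± 0.85 and is uncertain. RFPL4A, PAX2, RAI2, KIF1A and DMBT1 were tested in only 5 lines, and CCND2, CHST1, PRIMA1, GATA4 and HCN4 in 6. Elsewhere their direction rests on few counts. Falls were smaller: the polarity gene PARD6A fell by 0.67 ± 0.10, ZBED2 by 0.55 ± 0.13, the granule proteoglycan gene SRGN by 0.55 ± 0.13, HSBP1L1 by 0.54 ± 0.12 and LY6K by 0.49 ± 0.10. CYB5B fell by 0.49 ± 0.10, KLHDC9 by 0.47 ± 0.11, NME3 by 0.47 ± 0.09 and TMEM238 by 0.46 ± 0.13. TMEM238 (adjusted p = 0.048) missed the threshold without any 1 line (adjusted p of 0.0559 to 0.104) and with library totals (0.072), and KLHDC9 did so without HT1376, SW780, T24, TCCSUP or VMCUB (up to 0.0654) and with library totals (0.0525). GATA4 missed it without any line but HT1197 or KU1919 (up to 0.0909), KIF1A without HT1376, SW780, T24 or TCCSUP (up to 0.0663), and PAX2 without SW780 (0.0502). The same held for SRGN without HT1376, SW780, T24, 639V or TCCSUP (up to 0.0679), ZBED2 without SW780, T24, 639V, TCCSUP or VMCUB (up to 0.0733), and HSBP1L1 without HT1376, T24, 639V or VMCUB (up to 0.0688). The other 17 of the 25 named genes passed without any 1 line.

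Among the gene lists, the developmental transcription factors outside the HOX clusters were higher in the shared fit: 11 of 51 tested members were higher and 0 lower (20 and 0 adjusted over the list alone). The median was 0.80 (camera adjusted p = 5.56e-10, adjusted p = 0.135 with an estimated correlation). LHX2, a LIM homeobox factor, rose by 1.79 ± 0.35 and EMX1, a forebrain factor, by 3.05 ± 0.38. In the list of genes reported in the literature as repressed by EZH2, 5 of 22 tested members were higher and 0 lower (10 and 0 adjusted over the list alone). The median was 0.74 (camera adjusted p = 0.000106, adjusted p = 0.0581 with an estimated correlation). CDKN1C, a cyclin-dependent kinase inhibitor, rose by 2.24 ± 0.47 (adjusted p = 0.0241), and SFRP1, a secreted Wnt antagonist, by 1.67 ± 0.31 (adjusted p = 0.0174). In the neuronal genes 4 of 18 tested members were higher and 0 lower (7 and 0 adjusted over the list alone). The median was 0.56 (camera adjusted p = 0.000244, adjusted p = 0.342 with an estimated correlation). NEFL, a neurofilament gene, rose by 2.34 ± 0.48. In the MHC class II genes 1 of 11 tested members was higher and 0 lower (5 and 0 adjusted over the list alone). The median was 1.29 (camera adjusted p = 0.000612, adjusted p = 0.348 with an estimated correlation), and HLA-DMB rose by 2.26 ± 0.51. Among epithelial to mesenchymal transition genes 2 of 18 tested members were higher and 0 lower (2 and 0 adjusted over the list alone). The median was 0.41 (camera adjusted p = 0.000612, adjusted p = 0.0581 with an estimated correlation). FN1, which encodes fibronectin, rose by 0.64 ± 0.15. Among inflammatory cytokines and chemokines 3 of 27 tested members were higher and 0 lower (3 and 0 adjusted over the list alone). The median was 0.69 (camera adjusted p = 0.00183, adjusted p = 0.348 with an estimated correlation), and CXCL11 rose by 2.59 ± 0.65.

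In the fibroblast markers 1 of 12 tested members was higher and 0 lower (2 and 0 adjusted over the list alone). The median was 0.79 (camera adjusted p = 0.00473, adjusted p = 0.111 with an estimated correlation), and COL1A1 rose by 1.10 ± 0.20. In the endothelial markers 2 of 8 tested members were higher and 0 lower (3 and 0 adjusted over the list alone). The median was 0.64 (camera adjusted p = 0.0213, adjusted p = 0.348 with an estimated correlation). Camera also called higher the HOX genes (1 higher and 0 lower of 36, 0 and 0 adjusted over the list alone, camera adjusted p = 0.0142, adjusted p = 0.683 with an estimated correlation). Cancer/testis antigens were called higher too (3 higher and 0 lower of 24, 4 and 0 adjusted over the list alone, camera adjusted p = 0.0275, adjusted p = 0.348 with an estimated correlation). The housekeeping genes were called lower, with a median of -0.14 (0 higher and 2 lower of 15, 0 and 5 adjusted over the list alone, camera adjusted p = 0.000244, adjusted p = 0.342 with an estimated correlation). Also called lower, proliferation genes had a median of -0.10 (0 higher and 1 lower of 42, 0 and 0 adjusted over the list alone, camera adjusted p = 0.000411, adjusted p = 0.348 with an estimated correlation) and the cholesterol synthesis genes one of -0.15 (0 higher and 3 lower of 24, 0 and 6 adjusted over the list alone, camera adjusted p = 0.000974, adjusted p = 0.348 with an estimated correlation). TFRC, the transferrin receptor gene, fell by 0.28 ± 0.05, CCNA2, which encodes cyclin A2, by 0.17 ± 0.04 and EBP, a sterol isomerase gene of cholesterol synthesis, by 0.31 ± 0.07.

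In all, 1324 genes were higher and 799 lower among 18110 tested in the shared fit, 810 at least 2-fold higher and 1 at least 2-fold lower, and 359 to 733 at least 2-fold higher when 1 line was left out, the fewest without T24. Of these, 948 higher and 614 lower genes had the same direction in all 8 lines. Without HT1376 the HOX, cancer/testis and endothelial lists had camera adjusted p of 0.169, 0.299 and 0.0903, in ranges of 0.00122 to 0.169, 0.0275 to 0.299 and 0.00455 to 0.0903, and the cancer/testis list also missed the threshold without HT1197, KU1919, SW780 or TCCSUP and the HOX list without HT1197. Scaling by library totals left 110 genes lower, and leaving out 1 line gave 483 to 1060 higher and 107 to 739 lower genes, the fewest of each without T24.

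**Figure D2:**
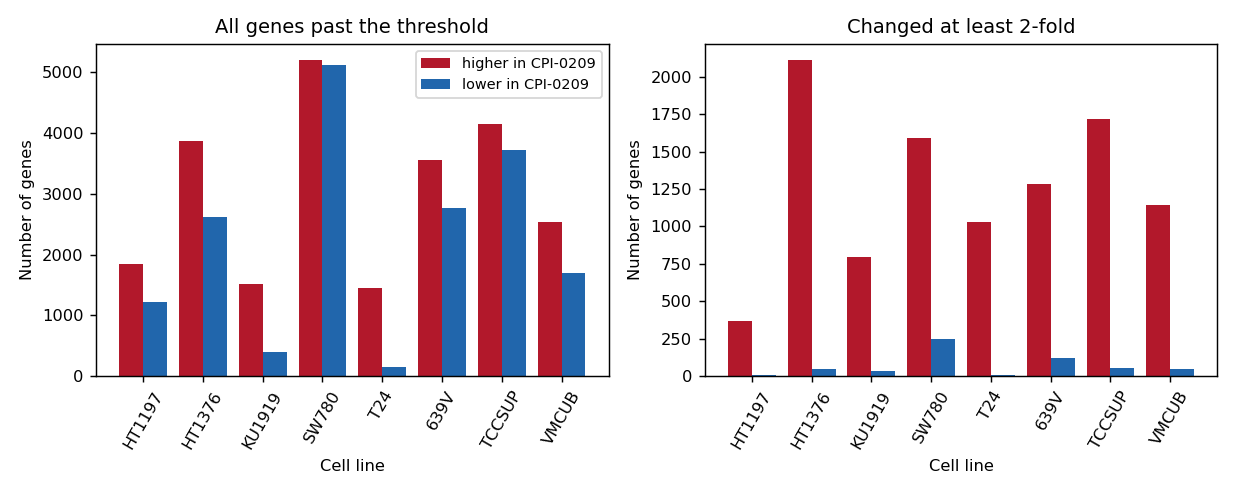
Number of genes (y axis) past the edgeR threshold in each cell line (x axis), red higher and blue lower in CPI-0209; the left panel counts all such genes and the right those changed at least 2-fold. SW780 had 5208 higher and 5114 lower genes on the left, but 1593 and 245 on the right.

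In HT1197 the largest named rise was that of CCND2, from 0.179 ± 0.0549 to 1.90 ± 0.0159 CPM (SD, n = 3), a change of 3.39 ± 0.24 (edgeR adjusted p = 5.97e-08). LGR5 rose by 2.67 ± 0.16, from 0.807 ± 0.231 to 5.16 ± 0.480 CPM. GNB4 rose by 2.55 ± 0.17, RET by 2.50 ± 0.26, MARK1 by 2.43 ± 0.25 and CYP24A1 by 2.34 ± 0.12. SLC19A2, a thiamine transporter gene, fell by 1.44 ± 0.14 (adjusted p = 1.78e-06). The readthrough gene NDUFC2-KCTD14, the T cell receptor segment TRBV12-5 and the pseudogene SMG1P4 had values of -1.82 ± 0.33, -0.95 ± 0.21 and -0.91 ± 0.15, and are uncertain because they share sequence with other loci.

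Proliferation genes were lower in HT1197: 0 of 42 tested members were higher and 28 lower (0 and 34 adjusted over the list alone). The median was -0.17 (camera adjusted p = 3.4e-16, adjusted p = 0.0492 with an estimated correlation). MCM4 and MCM2, which encode subunits of the replicative helicase, fell by 0.42 ± 0.04 and 0.31 ± 0.04, and the cell cycle factor gene FOXM1 fell by 0.23 ± 0.04. Epithelial to mesenchymal transition genes were higher: 12 of 18 tested members were higher and 0 lower (16 and 0 adjusted over the list alone). The median was 0.37 (camera adjusted p = 3.4e-16, adjusted p = 0.0182 with an estimated correlation). TGFB2 rose by 1.02 ± 0.05 and the gelatinase gene MMP2 by 0.71 ± 0.04. In the list from the EZH2 literature 12 of 19 tested members were higher and 0 lower (12 and 0 adjusted over the list alone). The median was 0.59 (camera adjusted p = 3.45e-12, adjusted p = 0.0397 with an estimated correlation). RUNX3, a transcription factor gene, rose by 1.34 ± 0.11. The developmental transcription factors were higher (15 higher and 0 lower of 32, 16 and 0 adjusted over the list alone, camera adjusted p = 5.55e-08, adjusted p = 0.0511 with an estimated correlation). So were the fibroblast markers (6 higher and 0 lower of 12, 6 and 0 adjusted over the list alone, camera adjusted p = 8.46e-06, adjusted p = 0.0492 with an estimated correlation), and LUM, which encodes lumican, rose by 1.45 ± 0.07. Basal and squamous genes were higher by camera (10 higher and 3 lower of 24, 12 and 3 adjusted over the list alone, camera adjusted p = 0.000171, adjusted p = 0.0764 with an estimated correlation). KRT6A, a keratin gene with near-identical copies, rose by 0.77 ± 0.04. Neuronal genes (6 higher and 0 lower of 11, 6 and 0 adjusted over the list alone, camera adjusted p = 0.00881, adjusted p = 0.113 with an estimated correlation) included NEFL, which rose by 1.41 ± 0.26. HOX genes (5 higher and 0 lower of 23, 5 and 0 adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.165 with an estimated correlation) included HOXC13, which rose by 0.44 ± 0.09. Cyclin-dependent kinase inhibitors (3 higher and 0 lower of 8, 3 and 0 adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.339 with an estimated correlation) included CDKN2B, which rose by 0.42 ± 0.05. Cytokines (8 higher and 0 lower of 18, 9 and 0 adjusted over the list alone, camera adjusted p = 0.0311, adjusted p = 0.165 with an estimated correlation) included IL11, which rose by 1.00 ± 0.14. Housekeeping genes were called lower (0 higher and 3 lower of 15, 0 and 5 adjusted over the list alone, camera adjusted p = 0.0138, adjusted p = 0.279 with an estimated correlation). In all, 1844 genes were higher and 1215 lower of 15579 tested, 369 and 5 of them by at least 2-fold, and 5 to 16 at least 2-fold lower leaving out 1 library, the most without CPI-0209 replicate 2. The share of higher calls was 60.3%, and 75.6% with library totals, which gave 685 lower genes. Leaving out DMSO replicate 2 took the cytokine list to a camera adjusted p of 0.0551, in a range of 0.0189 to 0.0551, and the lower genes to 709.

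In HT1376 the MHC class II genes, which present antigen to helper T cells, rose together: 12 of 12 tested members were higher and 0 lower (12 and 0 adjusted over the list alone). The median was 5.37 (camera adjusted p = 1.55e-56, adjusted p = 0.0158 with an estimated correlation). The invariant chain gene CD74 went from 6.02 ± 1.45 to 261 ± 9.00 CPM (SD, n = 3), a change of 5.43 ± 0.14, and HLA-DRA rose by 5.96 ± 0.12. Basal and squamous genes were higher: 23 of 29 tested members were higher and 2 lower (23 and 2 adjusted over the list alone). The median was 1.16 (camera adjusted p = 5.95e-18, adjusted p = 0.0158 with an estimated correlation). KRT1, a keratin of differentiated epidermis, rose by 2.59 ± 0.09, and S100A8, a calcium-binding alarmin gene, by 2.10 ± 0.09. Cytokines and chemokines rose too: 20 of 28 tested members were higher and 4 lower (20 and 4 adjusted over the list alone). The median was 1.66 (camera adjusted p = 1.17e-12, adjusted p = 0.0158 with an estimated correlation). CXCL10 rose by 4.75 ± 0.12 and CXCL1 by 3.59 ± 0.14. Of the leukocyte markers 3 of 7 tested members were higher and 1 lower (3 and 1 adjusted over the list alone), and camera did not call the list (camera adjusted p = 0.432, adjusted p = 0.517 with an estimated correlation). ITGAM, an integrin gene of myeloid cells, rose by 2.57 ± 0.14, CD3E, a T cell receptor subunit gene, by 1.24 ± 0.37 and CSF1R, the gene of a macrophage growth factor receptor, by 1.11 ± 0.10, while CD14 fell by 1.28 ± 0.10. PTPRC was at 0.401 ± 0.172 CPM with DMSO and 0.523 ± 0.127 CPM with CPI-0209, and TYROBP, LYZ and MS4A1 had 0 counts in all 6 libraries.

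Developmental transcription factors were higher in HT1376: 32 of 42 tested members were higher and 2 lower (32 and 2 adjusted over the list alone). The median was 2.64 (camera adjusted p = 2.96e-10, adjusted p = 0.0158 with an estimated correlation). MSX1 rose by 4.17 ± 0.16 and LHX2 by 2.90 ± 0.14. In the list from the EZH2 literature 13 of 19 tested members were higher and 3 lower (13 and 3 adjusted over the list alone). The median was 0.86 (camera adjusted p = 0.000149, adjusted p = 0.0488 with an estimated correlation). CDKN1C rose by 5.49 ± 0.15 and the Wnt inhibitor gene DKK1 by 1.95 ± 0.08. Neuronal genes (7 higher and 0 lower of 12, 7 and 0 adjusted over the list alone, camera adjusted p = 0.000184, adjusted p = 0.0488 with an estimated correlation) included CHGA, which encodes chromogranin A, higher by 2.88 ± 0.09. Epithelial to mesenchymal transition genes (10 higher and 1 lower of 14, 11 and 1 adjusted over the list alone, camera adjusted p = 0.000296, adjusted p = 0.0488 with an estimated correlation) included TWIST1, higher by 2.85 ± 0.16. Endothelial markers (5 higher and 0 lower of 7, 6 and 0 adjusted over the list alone, camera adjusted p = 0.00148, adjusted p = 0.136 with an estimated correlation) included PECAM1, which rose by 2.33 ± 0.13. HOX genes (8 higher and 0 lower of 10, 9 and 0 adjusted over the list alone, camera adjusted p = 0.00339, adjusted p = 0.146 with an estimated correlation) included HOXC13, which rose by 2.15 ± 0.20. MHC class I genes (12 higher and 0 lower of 19, 13 and 0 adjusted over the list alone, camera adjusted p = 0.0109, adjusted p = 0.488 with an estimated correlation) included TAP1, which rose by 0.90 ± 0.06. Fibroblast markers (6 higher and 2 lower of 10, 6 and 2 adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.13 with an estimated correlation) included COL1A1, which rose by 1.67 ± 0.05, and COL3A1, which fell by 1.24 ± 0.05. Luminal genes (12 higher and 2 lower of 23, 13 and 3 adjusted over the list alone, camera adjusted p = 0.0211, adjusted p = 0.238 with an estimated correlation) included GRHL3, which rose by 2.25 ± 0.08. The 6 higher genes that the naming rule took by fitted change were CT47A3, CT47A4, CT47A5, CT47A8, CT47A9 and CT47A10, cancer/testis copies on chromosome X. Each had 0 counts with DMSO and 181 with CPI-0209, at least 68.7-fold higher against a floor of 3 counts over the group. As near-identical paralogs they are uncertain. The kinase gene WNK4 fell by 1.51 ± 0.21, the proteoglycan gene SPOCK2 by 1.49 ± 0.19, the junctional gene JAM2 by 1.43 ± 0.20 and the pseudogene SINHCAFP3, uncertain for its parent gene's reads, by 2.29 ± 0.36. In all, 3875 genes were higher and 2619 lower of 16346 tested, 2113 and 43 of them by at least 2-fold, and leaving out 1 library gave 1587 to 3198 lower genes, the fewest without CPI-0209 replicate 3.

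In KU1919 the named higher genes had at most 3 counts with DMSO. EYA2, a transcriptional coactivator gene, had 1 count with DMSO and 153 with CPI-0209, a ratio of 168 (95% counting interval 29.6 to 6657), and KCNA2, a potassium channel gene, 1 and 132, a ratio of 144 (95% counting interval 25.5 to 5749). CCND2 had 3 and 284, a ratio of 104 (95% counting interval 35.1 to 505). GPR50, an orphan receptor related to melatonin receptors, had 0 counts with DMSO and 1.60 ± 0.736 CPM with CPI-0209, at least 61.4-fold higher. SCEL, which encodes sciellin of the cornified envelope, fell by 2.26 ± 0.16, from 16.6 ± 0.541 to 3.49 ± 0.807 CPM (edgeR adjusted p = 0.000269). IL36RN, an interleukin receptor antagonist gene, fell by 1.90 ± 0.24, CT62 by 1.89 ± 0.18 and the metalloprotease gene ADAMTS6 by 1.86 ± 0.15. RFPL4A and the pseudogene ZRSR2P1, at least 107-fold and 43.6-fold higher, are uncertain for their copies.

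Developmental transcription factors were higher in KU1919: 29 of 57 tested members were higher and 1 lower (36 and 3 adjusted over the list alone). The median was 0.69 (camera adjusted p = 1.27e-22, adjusted p = 0.0999 with an estimated correlation). LHX1 rose by 4.75 ± 0.14. Neuronal genes were higher: 9 of 14 tested members were higher and 2 lower (11 and 2 adjusted over the list alone). The median was 1.26 (camera adjusted p = 8.42e-12, adjusted p = 0.0364 with an estimated correlation). SLC17A7, a glutamate transporter gene, rose by 2.32 ± 0.14 and NEFL by 1.54 ± 0.09. The p53 target genes were called higher (8 higher and 0 lower of 25, 10 and 0 adjusted over the list alone, camera adjusted p = 0.00492, adjusted p = 0.168 with an estimated correlation). The death receptor gene FAS rose by 0.92 ± 0.10 and BTG2 by 0.77 ± 0.08. Basal and squamous genes were called lower (1 higher and 4 lower of 18, 1 and 7 adjusted over the list alone, camera adjusted p = 0.0431, adjusted p = 0.582 with an estimated correlation). COL17A1, a hemidesmosome collagen gene, fell by 0.95 ± 0.14, although KRT13 rose by 2.05 ± 0.12. Fibroblast markers were called higher (3 higher and 0 lower of 7, 6 and 0 adjusted over the list alone, camera adjusted p = 5.41e-05, adjusted p = 0.206 with an estimated correlation), with THY1 up by 0.95 ± 0.10. EZH2-literature genes were called higher (10 higher and 1 lower of 22, 11 and 2 adjusted over the list alone, camera adjusted p = 5.41e-05, adjusted p = 0.206 with an estimated correlation), with SFRP1 up by 2.35 ± 0.11. Luminal genes were called higher (8 higher and 1 lower of 22, 8 and 3 adjusted over the list alone, camera adjusted p = 0.0118, adjusted p = 0.22 with an estimated correlation), with ELF3 up by 1.27 ± 0.08. MHC class I genes were called higher (5 higher and 0 lower of 19, 6 and 0 adjusted over the list alone, camera adjusted p = 0.0143, adjusted p = 0.342 with an estimated correlation), with PSMB8 up by 1.05 ± 0.13. Epithelial to mesenchymal transition genes (7 higher and 1 lower of 20, 8 and 1 adjusted over the list alone, camera adjusted p = 0.0156, adjusted p = 0.206 with an estimated correlation) included TGFB2, up by 1.25 ± 0.18. HOX genes (9 higher and 0 lower of 36, 14 and 0 adjusted over the list alone, camera adjusted p = 0.0164, adjusted p = 0.342 with an estimated correlation) included HOXD13, up by 1.08 ± 0.12. In all, 1510 genes were higher and 389 lower of 16241 tested, 792 and 33 of them by at least 2-fold, and 26 to 57 at least 2-fold lower leaving out 1 library, the most without CPI-0209 replicate 3. CPI-0209 replicate 1 stood apart, with an SD of log2 deviations from its group of 0.285 against 0.146 and 0.174 in the other CPI-0209 libraries and a Spearman correlation of -0.732 with transcript length. Leaving out 1 library gave 858 to 3047 higher and 113 to 2375 lower genes, the fewest without DMSO replicate 1 and the most without CPI-0209 replicate 1. Without the latter the HOX list had a camera adjusted p of 0.109, in a range of 0.00185 to 0.109. Without DMSO replicate 1, 2 or 3 the basal list had 0.0565, 0.0799 or 0.0689, in a range of 0.00533 to 0.0799.

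SW780 had the most called genes, and its luminal urothelial genes were lower: 2 of 25 tested members were higher and 17 lower (2 and 17 adjusted over the list alone). The median was -0.26 (camera adjusted p = 4.42e-05, adjusted p = 0.339 with an estimated correlation). UPK1B and UPK3B, which encode uroplakins of the urothelial surface, fell by 1.31 ± 0.04 and 1.51 ± 0.06. CEACAM6, an adhesion glycoprotein gene, fell by 2.05 ± 0.05, from 144 ± 2.94 to 34.8 ± 1.45 CPM (SD, n = 3, edgeR adjusted p = 3.54e-16). The drug efflux transporter gene ABCG2 fell by 2.13 ± 0.06, from 73.6 ± 2.08 to 16.9 ± 1.69 CPM. TLR7, a sensor of RNA, fell by 2.10 ± 0.12. GATA4 had 0 counts with DMSO and 2.63 ± 0.469 CPM with CPI-0209, at least 102-fold higher, and CCND2 had 1 and 559 counts, a ratio of 462 (95% counting interval 82.6 to 18290). GAGE2E, CT47A11, RFPL4A and the pseudogenes FAM90A13P and FTH1P10 also passed the threshold, the first 4 higher and FTH1P10 lower, at -2.63 ± 0.29, and all 5 are uncertain because of near-identical copies.

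Basal and squamous genes of SW780 were called higher: 13 of 21 tested members were higher and 1 lower (13 and 1 adjusted over the list alone). The median was 0.33 (camera adjusted p = 0.0196, adjusted p = 0.339 with an estimated correlation). KRT5, a keratin of basal cells, rose by 2.15 ± 0.10. Developmental transcription factors were higher: 31 of 43 tested members were higher and 2 lower (32 and 2 adjusted over the list alone). The median was 1.24 (camera adjusted p = 3.25e-06, adjusted p = 0.288 with an estimated correlation). FOXA2 rose by 2.74 ± 0.18. In the EZH2-literature list 16 of 21 tested members were higher and 2 lower (16 and 2 adjusted over the list alone). The median was 0.88 (camera adjusted p = 4.37e-05, adjusted p = 0.0955 with an estimated correlation). PIK3IP1, an inhibitor of phosphoinositide kinase, rose by 1.71 ± 0.06 and SFRP1 by 1.78 ± 0.07. HOX genes (18 higher and 3 lower of 33, 18 and 3 adjusted over the list alone, camera adjusted p = 0.00161, adjusted p = 0.373 with an estimated correlation) included HOXD1, which rose by 1.96 ± 0.11. Cancer/testis antigens (9 higher and 4 lower of 20, 9 and 4 adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.288 with an estimated correlation) included MAGEA1, which rose by 1.23 ± 0.19. Proliferation genes were called lower (1 higher and 31 lower of 42, 1 and 31 adjusted over the list alone, camera adjusted p = 4.42e-05, adjusted p = 0.288 with an estimated correlation), with BIRC5, which encodes survivin, falling by 0.86 ± 0.04. Cholesterol synthesis genes were called lower (1 higher and 20 lower of 24, 1 and 20 adjusted over the list alone, camera adjusted p = 8.64e-06, adjusted p = 0.0955 with an estimated correlation), and DHCR7 fell by 0.92 ± 0.04. MHC class I genes were called lower (3 higher and 14 lower of 19, 3 and 15 adjusted over the list alone, camera adjusted p = 5.36e-05, adjusted p = 0.288 with an estimated correlation), and HLA-C fell by 1.03 ± 0.05. Housekeeping genes were called lower (0 higher and 13 lower of 15, 0 and 13 adjusted over the list alone, camera adjusted p = 1.35e-06, adjusted p = 0.184 with an estimated correlation), and PGK1 fell by 1.04 ± 0.04. In all, 5208 genes were higher and 5114 lower of 16897 tested, 1593 and 245 of them by at least 2-fold. Library totals moved the median of all SW780 genes by 0.201, giving 8499 higher and 2839 lower genes and a share of higher calls of 75% against 50.5%. Under that scaling 6 luminal genes were higher and 9 lower, 9 and 15 proliferation genes, 4 and 15 cholesterol genes, 4 and 10 MHC class I genes and 2 and 10 housekeeping genes, with medians of -0.06, -0.05, -0.23, -0.22 and -0.24. Mitochondrial transcripts held 4.63% to 5.26% of DMSO and 5.89% to 6.18% of CPI-0209 counts.

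In T24, CCND2 rose from 0.0540 ± 0.0502 to 10.6 ± 1.20 CPM (SD, n = 3), by 7.67 ± 0.42 (edgeR adjusted p = 0.000175). PAX2 had 1 count with DMSO and 379 with CPI-0209, a ratio of 350.2 (95% counting interval 62.5 to 13870). ST8SIA2, a polysialic acid synthase gene, had 0 counts with DMSO and 1.93 ± 0.235 CPM with CPI-0209, at least 78.5-fold higher. PRIMA1 had 2 and 432 counts, a ratio of 199.6 (95% counting interval 54.9 to 1653), and DMBT1 had 2 and 324, a ratio of 149.7 (95% counting interval 41.1 to 1241). TP63, a transcription factor of basal epithelium, fell by 3.33 ± 0.82 (adjusted p = 0.0457), the glucuronosyltransferase gene UGT2B7 by 1.24 ± 0.25, TM4SF19 by 1.28 ± 0.27 and SMIM11, which has a near-identical copy, by 1.72 ± 0.39. RFPL4AL1, with 1 and 384 counts, is uncertain for its copy RFPL4A.

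Developmental transcription factors were higher in T24: 15 of 38 tested members were higher and 1 lower (18 and 3 adjusted over the list alone). The median was 0.53 (camera adjusted p = 2.86e-08, adjusted p = 0.0475 with an estimated correlation). SOX21 rose by 3.75 ± 0.19 and FOXF1 by 1.57 ± 0.10. Fibroblast markers were higher: 4 of 8 tested members were higher and 0 lower (4 and 0 adjusted over the list alone). The median was 0.94 (camera adjusted p = 5.49e-06, adjusted p = 0.127 with an estimated correlation). The surface glycoprotein gene THY1 rose by 4.58 ± 0.28 and the growth factor receptor gene PDGFRB by 2.17 ± 0.24. Endothelial markers were higher: 4 of 6 tested members were higher and 0 lower (4 and 0 adjusted over the list alone). The median was 1.12 (camera adjusted p = 0.000822, adjusted p = 0.127 with an estimated correlation). TIE1 rose by 1.43 ± 0.13. Epithelial to mesenchymal transition genes (5 higher and 0 lower of 17, 5 and 0 adjusted over the list alone, camera adjusted p = 0.00635, adjusted p = 0.446 with an estimated correlation) included MMP2, up by 3.95 ± 0.20. Cancer/testis antigens were called higher (5 higher and 0 lower of 12, 5 and 1 adjusted over the list alone, camera adjusted p = 0.00635, adjusted p = 0.446 with an estimated correlation), with PAGE1 up by 2.66 ± 0.35. MHC class II genes were called higher (3 higher and 0 lower of 10, 5 and 0 adjusted over the list alone, camera adjusted p = 0.0307, adjusted p = 0.25 with an estimated correlation), with HLA-DPA1 up by 0.45 ± 0.09. EZH2-literature genes were called higher (7 higher and 1 lower of 20, 7 and 2 adjusted over the list alone, camera adjusted p = 0.0444, adjusted p = 0.25 with an estimated correlation), with CDKN1C up by 2.85 ± 0.23. In all, 1452 genes were higher and 144 lower of 15492 tested, 1032 and 8 of them by at least 2-fold, where the lower number ranged from 4 to 81 leaving out 1 library, the most without DMSO replicate 3. CPI-0209 replicate 3 and DMSO replicate 2 stood apart, with SDs of log2 deviations of 0.245 and 0.19 and correlations of -0.608 and -0.404 with transcript length, and without both there were 2446 higher and 1395 lower genes. Leaving out 1 library gave 905 to 1677 higher and 31 to 188 lower genes, the fewest without CPI-0209 replicate 2. Without that library TP63, TM4SF19, UGT2B7 and SMIM11 had adjusted p of 0.162, 0.0583, 0.101 and 0.128, and each also missed the threshold without at least 1 other. Over all alternatives their adjusted p ranged from 4.52e-07 to 0.242, 2.28e-05 to 0.0902, 0.000313 to 0.101 and 0.000142 to 0.128. Camera adjusted p of the cancer/testis list was 0.75 without DMSO replicate 3 and 0.221 without CPI-0209 replicate 3, in a range of 0.00278 to 0.75. That of the MHC class II list was 0.0995 without CPI-0209 replicate 3 and 0.0642 without DMSO replicate 2, in a range of 0.0176 to 0.224. That of the EZH2-literature list was 0.0642 and 0.0676 without DMSO replicates 2 and 3, in a range of 0.00898 to 0.0676.

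In 639V the chemokine gene CCL2 had 0 counts in all 3 DMSO libraries and 10.8 ± 0.799 CPM (SD, n = 3) with CPI-0209, at least 397-fold higher (edgeR adjusted p = 5.09e-11). MYOCD, which encodes the smooth muscle coactivator myocardin, was at least 229-fold higher, the glycoprotein gene OLFM4 at least 198-fold, the zinc finger gene ZNF536 at least 121-fold and GPR50 at least 85.0-fold. BMP5, a bone morphogenetic protein gene, had 3 and 2067 counts, a ratio of 542 (95% counting interval 185 to 2631). TNFSF18, a ligand of the T cell receptor GITR, fell by 3.83 ± 0.16, from 5.41 ± 0.323 to 0.378 ± 0.0507 CPM. The collagen gene COL3A1 fell by 2.29 ± 0.10, the protocadherin gene PCDH11X by 2.15 ± 0.23 and the pseudogene WFDC21P, uncertain for shared reads, by 2.16 ± 0.17.

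HOX genes were lower as a list in 639V: 7 of 36 tested members were higher and 18 lower (8 and 18 adjusted over the list alone). The median was -0.19 (camera adjusted p = 0.00159, adjusted p = 0.163 with an estimated correlation), HOXB8 at -0.87 ± 0.06 and HOXB6 at -0.77 ± 0.05. Neuronal genes were higher: 8 of 13 tested members were higher and 0 lower (8 and 0 adjusted over the list alone). The median was 0.82 (camera adjusted p = 9.11e-05, adjusted p = 0.163 with an estimated correlation). SYP, which encodes synaptophysin, rose by 1.34 ± 0.07 and SLC17A7 by 2.43 ± 0.09. In the EZH2-literature list 11 of 21 tested members were higher and 4 lower (11 and 4 adjusted over the list alone). The median was 0.59 (camera adjusted p = 0.000898, adjusted p = 0.163 with an estimated correlation). Its member SLIT2, an axon guidance gene, rose by 6.41 ± 0.23, and DKK1 fell by 1.51 ± 0.04. MHC class II genes were higher: 6 of 11 tested members were higher and 0 lower (6 and 0 adjusted over the list alone). The median was 1.37 (camera adjusted p = 0.00874, adjusted p = 0.373 with an estimated correlation). HLA-DPB1 rose by 2.73 ± 0.21. Epithelial to mesenchymal transition genes were higher: 9 of 16 tested members were higher and 1 lower (9 and 2 adjusted over the list alone). The median was 0.30 (camera adjusted p = 0.0086, adjusted p = 0.163 with an estimated correlation). TGFBI rose by 2.43 ± 0.12. In all, 3563 genes were higher and 2759 lower of 16126 tested, 1282 and 122 of them by at least 2-fold. The share of higher calls was 56.4%, and 71.9% with library totals, which gave 1655 lower genes.

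In TCCSUP the type I interferon-stimulated genes rose together: 30 of 36 tested members were higher and 3 lower (30 and 3 adjusted over the list alone). The median was 0.72 (camera adjusted p = 7.69e-22, adjusted p = 0.0401 with an estimated correlation). IFI44L rose by 2.92 ± 0.08, from 13.8 ± 0.923 to 105 ± 9.41 CPM (SD, n = 3, edgeR adjusted p = 1.78e-11), the antiviral GTPase gene MX1 by 1.65 ± 0.06 and OAS2 by 1.80 ± 0.06. MHC class II genes were higher: 10 of 11 tested members were higher and 0 lower (10 and 0 adjusted over the list alone). The median was 1.82 (camera adjusted p = 0.00013, adjusted p = 0.0945 with an estimated correlation). CD74 rose by 1.82 ± 0.08. FXYD6 rose by 7.14 ± 0.13 and PROM1, the gene of the stem cell antigen prominin, by 6.54 ± 0.27. FOXF2, a forkhead factor gene, had 0 counts with DMSO and was at least 62.2-fold higher (adjusted p = 0.0173, 0.0822 without CPI-0209 replicate 1, and 7.31e-10 to 0.0822 over all alternatives). NKX1-2, a homeobox gene, had 2 and 473 counts, a ratio of 219.5 (95% counting interval 60.4 to 1818), and AMBN, the gene of the enamel protein ameloblastin, 1 and 253, a ratio of 235 (95% counting interval 41.8 to 9310). The metalloprotease gene ADAM8 fell by 1.70 ± 0.07 and TRIM31 by 1.42 ± 0.15. RFPL4A (2 and 437 counts) and the pseudogene ZRSR2P1 (-5.15 ± 0.67) are uncertain for their copies.

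Neuronal genes were higher in TCCSUP: 12 of 15 tested members were higher and 0 lower (12 and 0 adjusted over the list alone). The median was 1.03 (camera adjusted p = 1.09e-05, adjusted p = 0.0945 with an estimated correlation). NEFL rose by 4.98 ± 0.13. In the EZH2-literature list 10 of 19 tested members were higher and 4 lower (11 and 4 adjusted over the list alone). The median was 0.60 (camera adjusted p = 0.000586, adjusted p = 0.0945 with an estimated correlation). DAB2IP, a RAS GTPase activator gene, rose by 4.17 ± 0.14. Cytokines were higher: 16 of 24 tested members were higher and 4 lower (16 and 4 adjusted over the list alone). The median was 0.92 (camera adjusted p = 0.00113, adjusted p = 0.192 with an estimated correlation). CCL5 rose by 1.78 ± 0.10 and IL11 by 1.97 ± 0.13. Basal and squamous genes (9 higher and 3 lower of 20, 9 and 3 adjusted over the list alone, camera adjusted p = 0.0322, adjusted p = 0.192 with an estimated correlation) included KRT17, up by 1.79 ± 0.06. Developmental transcription factors (23 higher and 8 lower of 42, 25 and 10 adjusted over the list alone, camera adjusted p = 0.0131, adjusted p = 0.129 with an estimated correlation) included BARX1, up by 2.03 ± 0.14. Epithelial to mesenchymal transition genes (9 higher and 1 lower of 17, 10 and 2 adjusted over the list alone, camera adjusted p = 0.00518, adjusted p = 0.338 with an estimated correlation) included TGFBI, up by 1.42 ± 0.05. Stress response genes (9 higher and 1 lower of 22, 9 and 1 adjusted over the list alone, camera adjusted p = 0.0322, adjusted p = 0.462 with an estimated correlation) included ATF3, up by 1.56 ± 0.07. Cancer/testis antigens (11 higher and 1 lower of 18, 11 and 1 adjusted over the list alone, camera adjusted p = 0.0322, adjusted p = 0.455 with an estimated correlation) included TEX15, up by 2.12 ± 0.25. Cholesterol synthesis genes were called lower (3 higher and 17 lower of 24, 3 and 18 adjusted over the list alone, camera adjusted p = 0.00571, adjusted p = 0.309 with an estimated correlation). The sterol isomerase gene EBP fell by 0.53 ± 0.06 and MSMO1, a sterol oxidase gene, by 0.60 ± 0.07. In all, 4149 genes were higher and 3721 lower of 16147 tested, 1720 and 55 of them by at least 2-fold. Without DMSO replicate 2 the stress response and cancer/testis lists had camera adjusted p of 0.0877 and 0.0705, in ranges of 0.00964 to 0.0877 and 0.0164 to 0.104, and without CPI-0209 replicate 3 the cancer/testis list had 0.0533. DMSO replicate 1 held 1.75% mitochondrial counts against 3.48% and 3.68% in the other DMSO libraries.

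In VMCUB, COL6A3, a collagen gene, rose by 4.89 ± 0.32, from 1.29 ± 0.784 to 38.5 ± 0.0225 CPM (SD, n = 3, edgeR adjusted p = 0.000142). The teneurin gene TENM3 rose by 4.77 ± 0.25, from 3.02 ± 1.27 to 82.5 ± 3.79 CPM. ALPG, the germ cell alkaline phosphatase gene, rose by 4.94 ± 0.32, FAM167A by 4.44 ± 0.35 and C2CD4C by 4.52 ± 0.37. MRC1, the mannose receptor gene of macrophages, had 3 and 201 counts, a ratio of 62.4 (95% counting interval 21.1 to 305). ANGPTL4, a secreted regulator of lipoprotein lipase, fell by 1.33 ± 0.07 (adjusted p = 8.37e-05) and the ion channel gene ZACN by 1.79 ± 0.39. SMIM11B, a copy of SMIM11, and the readthrough gene GJA9-MYCBP had values of -3.48 ± 0.53 and -1.31 ± 0.32 and are uncertain.

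Fibroblast markers were higher in VMCUB (7 higher and 0 lower of 8, 7 and 0 adjusted over the list alone, camera adjusted p = 9.07e-07, adjusted p = 0.103 with an estimated correlation). FBLN1 rose by 1.43 ± 0.08. Luminal urothelial genes were higher: 9 of 17 tested members were higher and 0 lower (10 and 1 adjusted over the list alone). The median was 0.45 (camera adjusted p = 0.000227, adjusted p = 0.156 with an estimated correlation). PPARG, a nuclear receptor of urothelial differentiation, rose by 1.23 ± 0.15 and FGFR3 by 1.20 ± 0.11. PRC1 subunits were higher: 8 of 19 tested members were higher and 0 lower (10 and 0 adjusted over the list alone). The median was 0.23 (camera adjusted p = 0.000577, adjusted p = 0.103 with an estimated correlation). CBX2, a chromodomain subunit gene, rose by 2.33 ± 0.07. Developmental transcription factors (20 higher and 0 lower of 40, 23 and 1 adjusted over the list alone, camera adjusted p = 8.46e-05, adjusted p = 0.103 with an estimated correlation) included LHX1, up by 2.06 ± 0.15. Interferon-stimulated genes (12 higher and 1 lower of 34, 13 and 1 adjusted over the list alone, camera adjusted p = 0.00849, adjusted p = 0.252 with an estimated correlation) included MX1, up by 1.01 ± 0.09. HOX genes (13 higher and 2 lower of 29, 15 and 5 adjusted over the list alone, camera adjusted p = 0.0138, adjusted p = 0.265 with an estimated correlation) included HOXC6, up by 3.08 ± 0.23. Endothelial markers (3 higher and 0 lower of 5, 3 and 0 adjusted over the list alone, camera adjusted p = 0.036, adjusted p = 0.252 with an estimated correlation) included ESAM, up by 1.23 ± 0.11. Housekeeping genes were called lower (0 higher and 5 lower of 15, 0 and 8 adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.423 with an estimated correlation). In all, 2540 genes were higher and 1698 lower of 15474 tested, 1140 and 46 of them by at least 2-fold (22 to 193 at least 2-fold lower leaving out 1 library, the most without DMSO replicate 3), and the share of higher calls was 59.9%, or 79.8% with library totals, which gave 826 lower genes. DMSO replicates 2 and 3 stood apart, with SDs of log2 deviations of 0.229 and 0.199 against 0.066 in replicate 1 and correlations of -0.507 and 0.559 with transcript length. Leaving out 1 library gave 1475 to 3807 higher and 297 to 3871 lower genes, the fewest higher without CPI-0209 replicate 2, the fewest lower without CPI-0209 replicate 1 and the most without DMSO replicate 3. ZACN missed the threshold without any library but DMSO replicate 3 (adjusted p up to 0.0746), and GJA9-MYCBP without DMSO replicate 1 or any CPI-0209 replicate (up to 0.0944). Over all alternatives their adjusted p ranged from 3.78e-06 to 0.123 and from 0.000166 to 0.0944. Without DMSO replicate 3 the HOX, interferon and endothelial lists had camera adjusted p of 0.107, 0.0625 and 0.14, in ranges of 0.00629 to 0.107, 0.00284 to 0.0625 and 0.0175 to 0.14, and without DMSO replicate 2 the endothelial list had 0.0903.

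**Figure D3:**
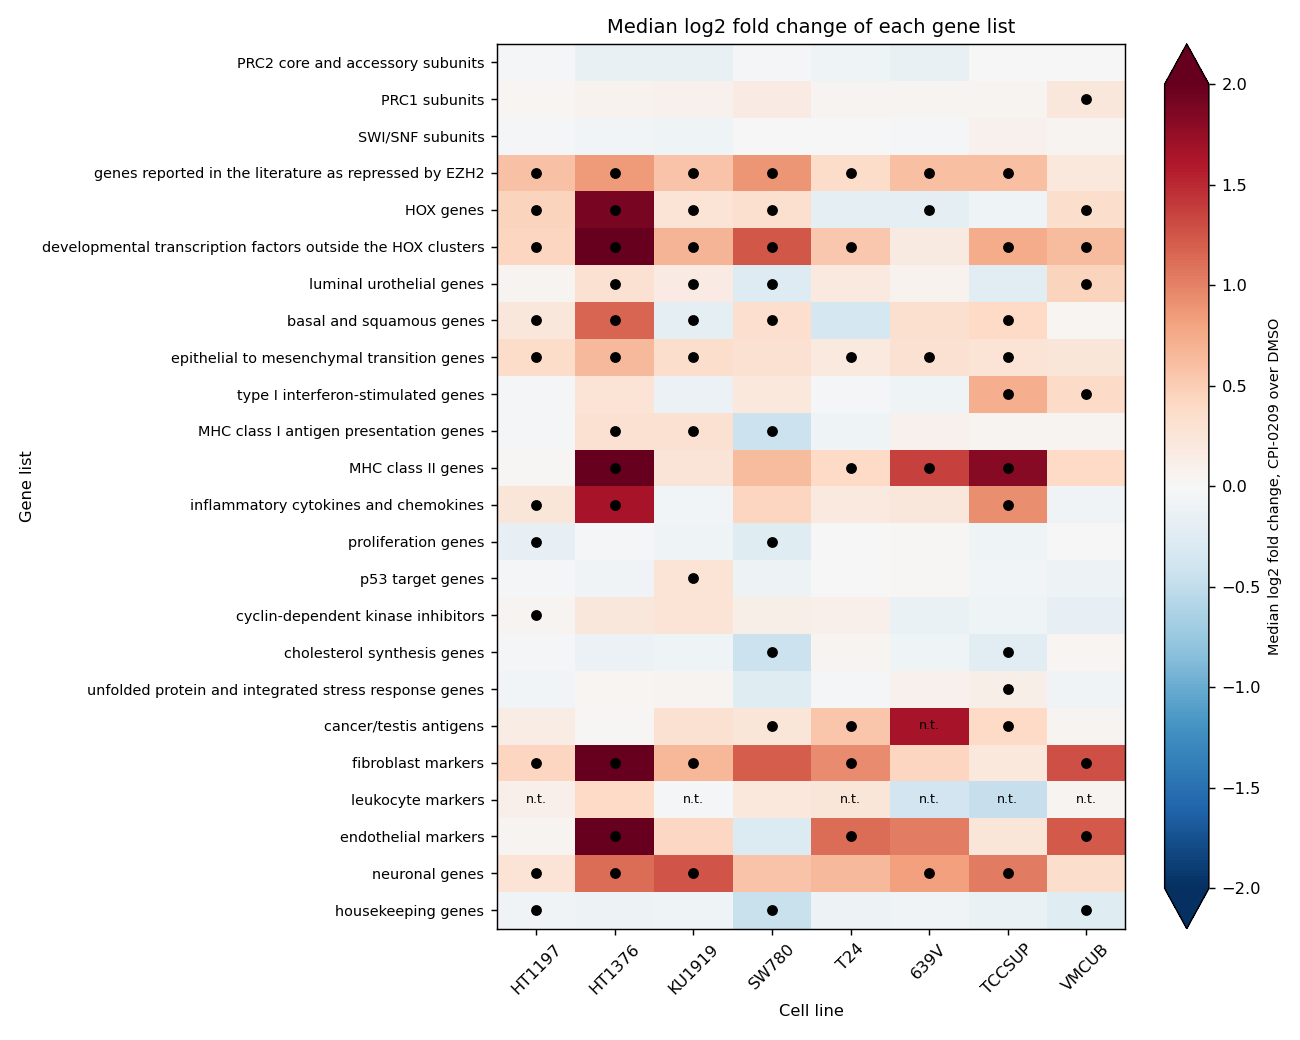
Median log2 fold change (color) of the tested members of each gene list (y axis) in each cell line (x axis); black dots mark lists called by camera with the preset correlation, n.t. marks lists with fewer than 5 tested members. MHC class II genes had medians from 0.03 to 5.37, and PRC2 subunits from -0.15 to -0.01.

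Over the 8 lines, camera called the developmental transcription factors higher in 7 lines and the EZH2-literature genes in 7, the epithelial to mesenchymal transition genes in 6, and the fibroblast markers and neuronal genes in 5 each, with 0 lines lower for all of these. With an estimated correlation they were higher in 2, 2, 2, 1 and 2 lines. HOX genes were higher in 5 lines and lower in 1, basal and squamous genes higher in 4 and lower in 1, luminal genes higher in 3 and lower in 1, and MHC class I genes higher in 2 and lower in 1. With an estimated correlation basal and squamous genes were higher in 1 line, and HOX, luminal and MHC class I genes were called in 0. MHC class II genes were higher in 4 lines, cytokines, cancer/testis antigens and endothelial markers in 3 each, and interferon-stimulated genes in 2, and with an estimated correlation MHC class II genes, cytokines and interferon-stimulated genes in 1 each and the others in 0. PRC1 subunits, p53 targets, cyclin-dependent kinase inhibitors and stress response genes were higher in 1 line each, and in 0 with an estimated correlation. Housekeeping genes were lower in 3 lines, proliferation genes and cholesterol synthesis genes in 2 each, and with an estimated correlation in 0, 1 and 0 lines. PRC2 subunits and SWI/SNF subunits were called in 0 of 8 lines, with medians from -0.15 to -0.01 and from -0.09 to 0.09. Leukocyte markers had enough tested members in 2 lines and were called in 0 of them, with medians of 0.40 in HT1376 and 0.21 in SW780. Of 74 list calls in single lines, 14 held with an estimated correlation.

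Next, the responses of the lines were compared. SERPINB2, a serine protease inhibitor gene, rose by 2.33 ± 0.05 in HT1376 and 2.45 ± 0.25 in SW780, and fell by 1.65 ± 0.08 in KU1919 (interaction adjusted p = 1.21e-25). ABCG2 rose by 1.97 ± 0.31 in 639V and fell by 2.13 ± 0.06 in SW780 and 1.24 ± 0.05 in TCCSUP (2.49e-22). CEACAM6 rose by 6.39 ± 0.54 in KU1919 and fell by 2.05 ± 0.05 in SW780 (1.08e-18), and SCEL rose by 1.62 ± 0.11 in HT1376 and fell by 2.26 ± 0.16 in KU1919 (1.08e-17). FST rose by 3.48 ± 0.13 in HT1376 and fell by 1.17 ± 0.11 in VMCUB (1.42e-22). ARRB1 rose by 1.75 ± 0.14 in VMCUB and fell by 1.08 ± 0.05 in SW780 (9.3e-23). ADAM8 rose by 1.29 ± 0.07 in HT1376 and fell by 1.70 ± 0.07 in TCCSUP (9.6e-23), and DKK1 rose by 1.95 ± 0.08 in HT1376 and fell by 1.51 ± 0.04 in 639V (4.29e-18). PSCA rose by 1.78 ± 0.12 in VMCUB and fell by 1.84 ± 0.11 in SW780 (1.73e-18). CALB1 rose by 1.60 ± 0.15 in TCCSUP and fell by 1.90 ± 0.05 in 639V (5.03e-18). Parentheses give adjusted p of edgeR's interaction F test. In all, 11611 of 19790 genes (58.7%) passed it, and 8998 to 12887 with 1 line left out. It took 1 spread per gene over all lines, so noise in KU1919, T24 and VMCUB may add calls. Of 3452 genes called higher in one line and lower in another, 113 changed at least 2-fold both ways, 111 of them past this test.

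Lines shared more calls than equal odds of a call for every tested gene would give. T24 and KU1919 shared 567 higher genes against 104.9 (ratio 5.4). 639V and SW780 shared 1946 against 997.7 (1.95), the other extreme of 28 pairs (median 2.83). For lower calls the ratio ran from 1.24 for KU1919 and SW780 to 8.26 for KU1919 and T24 (median 1.89). Opposite calls ran from 33 for KU1919 and T24 to 1132 for SW780 and 639V. Such counts and ratios depend on how many genes each line called. Across genes, not independent replicates, Pearson's r of log2 fold changes ran from 0.304 for KU1919 and VMCUB to 0.568 for T24 and TCCSUP. It was 0.483 for KU1919 and T24 and 0.463 for SW780 and 639V. Of 13011 genes tested in all 8 lines, 88 were higher in all 8 by edgeR and 80 by DESeq2. None was lower in all 8 by edgeR, against 14 at an unadjusted p under 0.05 and 4 by DESeq2. The 7 lower in 7 lines, chosen after their values were seen, were MXD1, CTNNAL1, RRAS2, DUSP5, GLUD1, TMEM87B and PGAM1.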

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

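The tests weighed here, of scaling, abundant genes, leukocyte transcripts, the interferon list and transcript length, were chosen after the result was seen, and the test of the difference between lines was planned. The 10 genes named for differences between lines were taken by their p in edgeR's interaction F test, so that they pass it follows from the choice. The adjusted p was 1.21e-25 for SERPINB2, 9.3e-23 for ARRB1, 9.6e-23 for ADAM8, 1.42e-22 for FST and 2.49e-22 for ABCG2. It was 1.08e-18 for CEACAM6, 1.73e-18 for PSCA, 4.29e-18 for DKK1, 5.03e-18 for CALB1 and 1.08e-17 for SCEL.

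Of the 25 genes named for the shared response, 23 also differed in size of response between lines by the same test, 14 of those higher and 9 of those lower. For the higher genes the adjusted p was 1.02e-18 for CCND2, 3.84e-17 for FXYD6, 2.57e-16 for KIF1A, 2.06e-15 for GATA4, 3.59e-14 for PAX2, 1.58e-13 for PRIMA1, 4.52e-13 for LGR5 and 2.28e-11 for LINGO1. It was 1e-08 for RFPL4A, 5.28e-07 for CHST1, 3.3e-06 for HCN4, 6.65e-06 for DMBT1, 0.000315 for RAI2 and 0.000431 for TEX15. For the lower genes it was 2.21e-12 for CYB5B, 2.9e-05 for ZBED2, 4.67e-05 for MXD1, 0.000188 for HSBP1L1, 0.000754 for LY6K, 0.00357 for NME3, 0.0203 for TMEM238, 0.0223 for PARD6A and 0.0449 for SRGN. SHH (0.0615) and KLHDC9 (0.423) did not pass.

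The first pattern is the excess of genes at least 2-fold higher over genes at least 2-fold lower, for example 2113 against 43 in HT1376. Library scaling argues poorly for it. The share of higher genes among 2-fold calls was at least 86.2% over the 8 lines under RLE factors and library totals. That low genes can rise but hardly fall was tested on genes with a mean of at least 10 CPM. SW780 was set apart after the values were seen. The mean counts treated libraries, so a gene low with DMSO can enter by rising. In the other 7 lines the share was at least 75.5% (95% exact binomial interval 67.9% to 82% in 639V). In SW780 it was 50.8%, 169 genes against 164 (45.2% to 56.2%). Release of repressed genes may account for the excess, but lack of room to fall stays open in all 8 lines. The 169 rises among these genes in SW780 outnumbered those of 5 of the 7 other lines, and its even share comes from its falls.

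The second pattern is the rise of MHC class II genes in HT1376. Leukocytes in the treated cultures would bring their own transcripts, but 7 of these, picked after the result was seen (PTPRC, TYROBP, FCER1G, LYZ, CD14, CD79A and MS4A1), summed to 1.19% of the CPM of CD74, and TYROBP, LYZ and MS4A1 had 0 counts in every library, which allows up to 3 counts against 24920 of CD74. The full list of 15 leukocyte markers went from 14.8 to 33.8 CPM, 12.9% of CD74, since ITGAM, CSF1R and CD3E rose, for which no explanation was tested. A type I interferon response would raise its target genes, but their median in HT1376 was 0.28, and 0.12 to 0.39 with 1 library left out. As a hypothesis, the rise may run through CIITA, the master regulator of class II transcription, in the tumor cells, where it went from 3.72 ± 0.0579 to 36.9 ± 6.81 CPM, and a response to interferon gamma stays untested.

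The third pattern is the small number of genes called lower in KU1919 (389) and T24 (144). Some libraries there followed transcript length, as did others, for example HT1376 DMSO replicate 1 (correlation -0.696) in a line with 2619 lower genes. Removing that trend gave 1847 lower genes in KU1919 and 295 in T24. In the other lines it gave less than 1.5 times as many, for example 2351 against 1698 in VMCUB. It also took higher genes in KU1919 from 1510 to 2338. Removal narrows spread within groups, which adds calls, so it cannot show that the trend hid falls. T24 without its 2 farthest libraries had 1395 lower genes. How much of the spread the trend covers, and whether cultures differed, was not tested.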

How the results depend on the processing

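The choices called added here (library totals, length trend, libraries far from their groups, list calls with libraries left out, HOX clusters by scaling) were chosen after the data were seen, the others before. RLE factors and thinning to the smallest library kept all 19 counts of calls within 1.5 times. Of the named genes the tests called, DESeq2 ended 3 calls, RLE factors 1, thinning 6, no filter on low counts 6, library totals 5, besides SUZ12 in SW780 that turned, and one fit of all libraries 9. With DESeq2, HT1197 had 1227 genes higher, KU1919 819 lower, T24 515 lower, VMCUB 2813 lower and the shared response 2483 higher and 2295 lower. Library totals gave 685 lower in HT1197, 8499 higher and 2839 lower in SW780, 90 lower in T24, 1655 in 639V, 826 in VMCUB and 110 in the shared response, and turned SUZ12 in SW780 from -0.148 to 0.054. In one fit of all 48 libraries HT1197 had 1063 higher and 199 lower, KU1919 2601 and 1995, T24 2762 and 1582, 639V 1366 lower and VMCUB 3880 lower. The mean of the 8 within-line effects gave 5482 higher and 5131 lower genes, and 5255 and 4855 with the replicate block. No filter on low counts gave 386 lower genes in the shared response, treatment alone without the line term 0 and 0 and no call of the 25 named genes, and leaving out the 4 libraries farthest from their groups 1681 lower. Removing the length trend gave 2338 higher and 1847 lower in KU1919 and 295 lower in T24, and T24 without its 2 farthest libraries had 2446 and 1395. The cause was not tested for any of these.

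Replicate numbers did not pair the samples: 6 of 24 same-numbered pairs correlated over 0.1, 0 lines had all 3, and 13 of 48 samples correlated best with their own number. With the number as a block HT1376 had 1470 lower genes and T24 26, and 6 calls of named genes ended: SUZ12 in HT1197, EZH2 in HT1376, SMIM11, TM4SF19 and UGT2B7 in T24 and EZH1 in VMCUB. The block also took the cancer/testis list of TCCSUP from a camera adjusted p of 0.0322 to 0.104, and the MHC class I, cytokine and housekeeping lists of 639V to 0.0286, 0.0367 and 0.0461, past the threshold.

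With 1 library left out, genes lower ranged from 709 to 1130 in HT1197 and from 1587 to 3198 in HT1376. In KU1919 they ranged from 858 to 3047 higher and 113 to 2375 lower, in T24 from 905 to 1677 and 31 to 188, and in VMCUB from 1475 to 3807 and 297 to 3871. With 1 line left out, the shared response ranged from 483 to 1060 higher and 107 to 739 lower. Over all alternatives, genes at least 2-fold lower ranged from 2 to 34 in HT1197, 41 to 68 in HT1376, 26 to 67 in KU1919, 122 to 326 in SW780, 4 to 176 in T24, 96 to 197 in 639V, 52 to 110 in TCCSUP and 22 to 193 in VMCUB, while each line's count at least 2-fold higher stayed within 1.5 times. In the shared response genes at least 2-fold higher ranged from 0, with treatment alone, to 1578, with the mean of within-line effects, and those at least 2-fold lower from 0 to 5. Depth limited genes with few counts, whose folds are bounds or carry wide counting intervals.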

Other observations

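The tests of HOX clusters and of EZH2 levels, and the genes changed 2-fold in all lines, were chosen after the result was seen, while the splits of the samples were planned. At least 2-fold rises in each of the 8 lines were called for 7 genes, LINGO1 and 6 others outside the named genes. ADAMTS2, a procollagen protease, rose by 1.44 to 5.04 on the log2 scale, NES, which encodes nestin, by 1.10 to 4.53, and PDLIM3, an actinin-binding gene, by 1.06 to 5.55. SLC30A3, a zinc transporter gene, rose by 1.12 to 3.38, RTN4RL2, a receptor of the Nogo family, by 1.49 to 4.37, and TMEM37 by 1.03 to 5.03. Genes at least 2-fold higher were mostly low at baseline: those under 1 CPM with DMSO made up 55.8% in KU1919 to 72.9% in HT1197, against 15.9% to 20.1% of all tested genes.

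HOX genes moved in both directions in SW780, 639V and TCCSUP, and those called in HT1197 (5), HT1376 (8) and KU1919 (9) were higher. T24 had 5 higher and 5 lower and VMCUB 13 and 2, but with library totals 5 and 0 and 14 and 0, so their falls depended on the scaling. In TCCSUP 2 called members of the HOXA and HOXB clusters were higher and 10 lower, against 6 higher and 1 lower in HOXC and HOXD (Fisher's exact test, two-sided p = 0.00627, 0.0502 adjusted over the 8 lines), and with library totals 2 and 8 against 6 and 1 (exact p = 0.0152, adjusted 0.103). In 639V the numbers were 3 and 13 against 4 and 5 (exact p = 0.205, adjusted 0.41), and with library totals 3 and 13 against 5 and 2 (exact p = 0.0257, adjusted 0.103). SW780 had 6 and 3 against 12 and 0 (exact p = 0.0632, adjusted 0.169), and 12 and 2 against 12 and 0 with library totals (exact p = 0.483, adjusted 1). A hypothesis is that the direction of a HOX gene may go with its cluster in TCCSUP, though neighbors in a cluster are not independent and no line passed the adjustment under TMM, RLE or library totals.

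Another hypothesis, that lines with more EZH2 respond with more genes, found no support. Over the 8 lines the level of EZH2 with DMSO and the number of genes at least 2-fold higher had Pearson's r = 0.156 (exact permutation p = 0.71, adjusted 0.73 over 2 relations) and Spearman's rho = 0 (exact permutation p = 1). Without HT1197 and 639V, the 2 lines farthest from the median, r was -0.498. For genes at least 2-fold lower r was 0.172 (exact permutation p = 0.73) and -0.206 without those lines. With 8 lines a relation of moderate size cannot be excluded.

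Other splits were compared with the real groups. In each line 10 splits exist, too few for a share under 0.05. The real split gave 3059 calls in HT1197, 6494 in HT1376, 1899 in KU1919 and 10322 in SW780. It gave 1596 in T24, 6322 in 639V, 7870 in TCCSUP and 4238 in VMCUB, and the highest other 0 in every line. For the shared response the real 1 of 100 splits gave 2123 genes and the highest other 1, so by rank chance is unlikely. For differences between lines the real 1 of 25 gave 11611 and the highest other 2111. Shuffling removes the response itself, so these gaps do not measure evidence or test differences between lines.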
